A study of Homo sapiens with 8 samples.

How the data were processed

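Flash-frozen human brain tissue was crosslinked with ultraviolet light at 400 mJ/cm2, and 50 mg was used per experiment with RNase I at 40 U, per the labels' protocols. RNA was taken from a gel region reaching 75 kDa above the protein, about 150 nt of RNA, and a random sequence of 10 bases was ligated to the cDNA. The labels give 8 libraries: 2 immunoprecipitations with an FXR1 antibody, 2 with an FMRP antibody, and 4 inputs. The inputs have no peak list and enter only through the enrichment over input. The design line of the series names 2 cell lines, whereas the labels of each library name brain; the labels were followed.

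The authors deposited 1 peak list per immunoprecipitated library, so replicates were not pooled. Per the submitters' processing notes the genome build was hg19 and the tools included cutadapt, STAR, GATK, Picard and SAMtools, without versions; the peak caller is not given in the sources used here. Each deposited list gives for every peak a log2 enrichment over input, a −log10 p (capped at 400) and a score. The score took 2 values in the deposited files, 1000 where log2 was at least 3 and −log10 p at least 3 and 200 elsewhere, in 8687 of 8687, 4347 of 4347, 9767 of 9767 and 19261 of 19261 peaks. These values are the authors' own and were used to describe, filter and rank peaks within a list.

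Peaks at or past both thresholds on the autosomes and chromosome X were the main set. Chromosome Y and the X-inactivation locus were left out at the start because the tissue came from people. The lists give no read counts. The deposited log2 values of a library fall on a ladder, so that the linear enrichment equals a constant times the ratio of 2 whole numbers, which were taken as immunoprecipitated and input reads. The constant, the ratio of input to immunoprecipitation depth, was set from the commonest value, taken as 3 reads over 1 input read. It was 38.4 and 41.0 for FXR1 replicates 1 and 2 and 7.57 and 3.72 for FMR1 replicates 1 and 2. A peak counted as resolved when whole numbers met the enrichment within a relative tolerance of 1e-05 and a binomial tail with those reads met the deposited −log10 p within 0.05 of its size; this held for 99.6%, 99.3%, 99.2% and 99.0% of peaks. Reads are therefore inferred. Between 77.5% and 83.1% of peaks had the smallest input value, 1 read. The ladder gives a ratio of depths and no library total, so absolute depth is unknown.

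Overlap of peaks needed at least 1 nt on the same strand, with Wilson 95% intervals, and was set against 100 draws in which each peak moved 500 to 5000 nt. Peaks of the 4 libraries that overlapped or touched on one strand were merged into regions. Jaccard indices, the pattern odds (regions called in exactly 2 libraries, the product of the counts of same-antibody pairs over the geometric mean of that of the other 2 pairings, with 2000 bootstrap resamples) and Fisher's exact test of set overlap were computed on these regions. Group means were compared by an exact two-sided permutation test over the 6 assignments of 4 libraries. Intervals and Fisher tests cover counting error only. Loci were peaks of any library chained at gaps of up to 10 kb on one strand; those with at least 10 peaks were tested by Fisher's exact test, with Benjamini-Hochberg adjustment. The tests, the main threshold and the rule for named regions (the 10 per antibody with the highest percentile rank in the lower of its 2 replicates) were fixed before the data were examined; the locus test, the read inference and the settings named as such were chosen after. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

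The computations were tested on simulated data. Of 5000 simulated peaks per library, 100% had their reads recovered. These peaks were made with the same ladder, starting at 3 reads over 1 input read, and the same binomial tail. Their recovery thus tests the computation and not those assumptions. With no antibody effect among 9832 simulated regions the pattern odds were 1.14 (95% interval 0.954 to 1.37), and with an effect among 10214 regions they were 4.93. Apart from list length, the libraries without an effect detected regions alike, so detection limits that differ by antibody were not simulated. For the test of FXR1 against FMR1 on loci, with 200 of 740 loci changed, 10.5% of those changed 2-fold, 78.0% of those changed 4-fold and 95.5% of those changed 8-fold were called, with 1, 3 and 4 false calls. The simulated loci held more peaks on average than the real ones, and replicates differed by counting error alone. The shares called are therefore likely too high, and the false calls too few, for these data.

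Alternatives were a stricter threshold (log2 of at least 4 and −log10 p of at least 5), every deposited peak, lists of equal length, peaks of at least 20 nt, reciprocal overlap of 50%, peaks within 50 nt, moves of 200 to 1000 nt, mitochondrial peaks added, at least 2 peaks per library, each library left out, and pairing by replicate number. An annotation or sequence of hg19 was not used here, so that no gene, exon or untranslated region is named, merged regions took the place of genes, and the planned gene lists, cell type markers, region shares, sequence content and transcript positions were not analysed here. Coordinates are as deposited, in hg19, counted from 1.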

Results

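RNA contacts of 2 related RNA-binding proteins were mapped in human brain tissue by eCLIP, in which RNA is crosslinked to protein with ultraviolet light, trimmed with RNase I, immunoprecipitated with its protein and sequenced beside a size-matched input. The antibodies were against FXR1 and against FMRP, the product of FMR1 and a member of the same protein family; the libraries of the second antibody are called FMR1 here. The series belongs to a study of RNA editing in autism spectrum disorder. Each antibody had 2 immunoprecipitated libraries, and each of these had its own input, so that 8 libraries are labelled and 4 have a peak list. The comparisons that the design allows are between replicates of one antibody and between the antibodies. The labels do not say whether replicates came from separate tissue, so permutation p-values measure only the spread between these libraries, which may be technical. P-values of Fisher's exact test, on pooled counts, cover counting error only and take no account of that spread.

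The FXR1 lists held 8640 and 4300 peaks past the threshold of log2 enrichment of at least 3 and −log10 p of at least 3 on the autosomes and chromosome X, and the FMR1 lists held 5723 and 7457. The mean was 6470 ± 3069 (SD, n = 2) for FXR1 and 6590 ± 1226 (SD, n = 2) for FMR1, and the antibodies were not distinguishable (exact permutation test, two-sided, p = 1; the smallest p that 2 against 2 libraries allow is 0.333). The lists nevertheless differed in what a peak stood for. Almost the whole FXR1 lists passed the threshold (99.7% of 8666 and 99.5% of 4322 deposited peaks), against 58.8% of 9737 and 38.8% of 19218 deposited FMR1 peaks. The reads behind each peak, inferred from the ladder of deposited enrichments, numbered 5 and 3 (medians) in FXR1 replicates 1 and 2 and 7 and 11 in FMR1 replicates 1 and 2. With no more than 1 input read, 3 immunoprecipitated reads sufficed to pass in each FXR1 library, 4 in FMR1 replicate 1 and 6 in FMR1 replicate 2. With the same minimum of 6 reads in each library, 4044 and 998 FXR1 peaks stood against 3500 and 7457 FMR1 peaks. This setting was chosen after seeing the data, and each FMR1 replicate 2 peak past the threshold already meets it. The log2 ratio of FXR1 to FMR1, taken as the difference between means of log2 counts, moved from −0.10 to −1.35. The arithmetic means at 6 or more reads were 2521 for FXR1 and 5478.5 for FMR1 (exact permutation test, two-sided, p = 0.667).

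Peaks were short and lay on both strands. Their median width was 46 and 44 nt in the FXR1 libraries and 52 and 59 nt in the FMR1 libraries, and between 51.0% and 52.5% of each list lay on the plus strand. The mean of the median widths was 45.0 ± 1.41 nt (SD, n = 2) for FXR1 and 55.5 ± 4.95 nt (SD, n = 2) for FMR1 (exact permutation test, two-sided, p = 0.333, the smallest possible). Peaks were gathered in clusters: after touching peaks were joined, 63.4% of the peaks of FXR1 replicate 1, 59.3% of FMR1 replicate 1 and 64.7% of FMR1 replicate 2 had another peak of the same library within 1 kb on the same strand. FXR1 replicate 2 stood apart with 37.5% (Wilson 95% interval 36.0 to 39.1%), and 49.2% of its peaks had no other within 10 kb, against 21.5 to 26.8% in the other 3 libraries.

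Replicates of one antibody shared far more peaks than displaced peaks would. Of the FXR1 replicate 2 peaks, 48.9% (Wilson 95% interval 47.4 to 50.4%, counting error only) overlapped a peak of FXR1 replicate 1 by at least 1 nt on the same strand, against a mean of 1.59% when each peak was moved 500 to 5000 nt. Of the FMR1 replicate 1 peaks, 63.0% (61.7 to 64.2%) overlapped a peak of FMR1 replicate 2, against 2.55% for moved peaks. None of 100 draws of moved peaks came near these shares. At 6 or more reads the share was 86.9% of 998 peaks for FXR1 and 81.2% of 3500 for FMR1. The order of the antibodies thus turned in this direction, from the shorter list to the longer, whose lengths were then 4044 and 7457. Regions in both replicates then numbered 837 for FXR1 and 2668 for FMR1, and the share in the other direction is not given here. In the main set the shares in the other direction were 24.9% of FXR1 replicate 1 peaks and 50.3% of FMR1 replicate 2 peaks. Overlap between the antibodies ranged as widely. Of the peaks of FMR1 replicates 1 and 2, 59.5% and 62.6% met a peak of FXR1 replicate 1, and 30.0% and 28.5% met one of FXR1 replicate 2. Of the peaks of FXR1 replicates 1 and 2, 40.2% and 39.3% met a peak of FMR1 replicate 1, and 53.5% and 47.4% met one of FMR1 replicate 2. The share that overlapped any other library rose with read support in every library over the ranges up to 10 to 19 reads. It was 23.5% and 29.5% at 3 reads in FXR1 replicates 1 and 2, and 96.7% and 98.6% at 10 to 19 reads. At 20 or more reads it was 99.6% in FXR1 replicate 1, 98.9% in FMR1 replicate 1 and 97.0% in FMR1 replicate 2. In FXR1 replicate 2 it was 83.2% (76.4 to 88.4%), and 17 of the 25 peaks without a partner there lay in the chromosome 11 locus described with the loci.

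**Figure D1:**
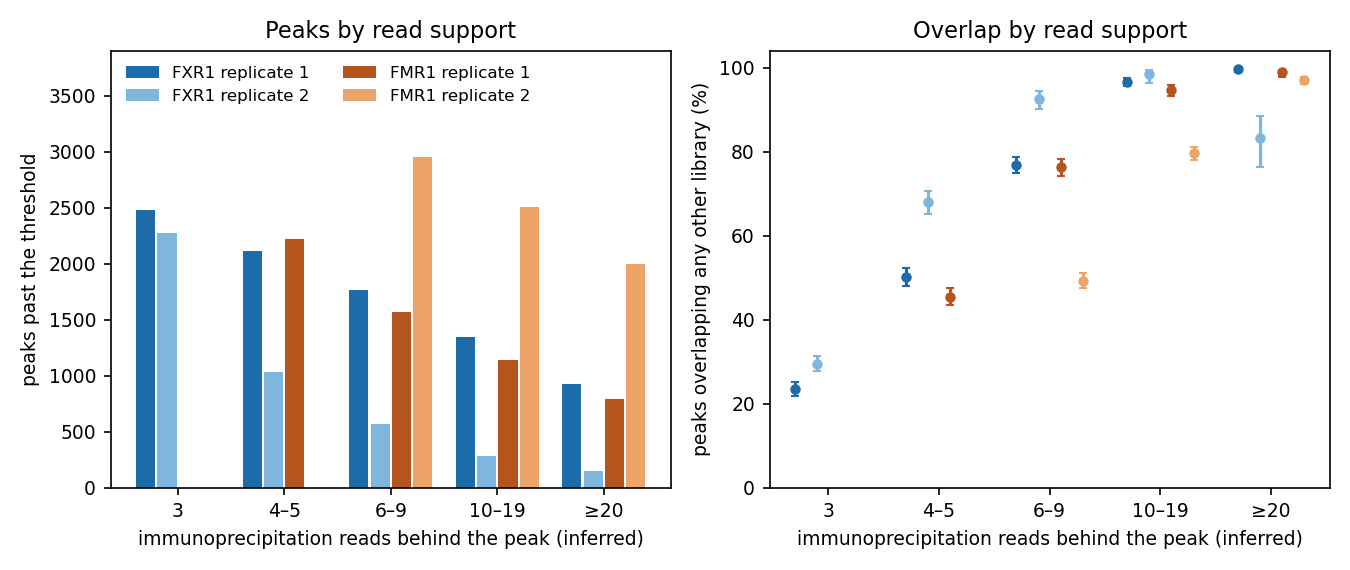
Left, number of peaks past the threshold (y axis) by the number of immunoprecipitation reads inferred behind each peak (x axis), 1 bar per library. Right, percent of those peaks that overlap a peak of any of the other 3 libraries, with Wilson 95% intervals as error bars. Overlap is 23.5% and 29.5% at 3 reads in the FXR1 libraries and 94.6% or more at 10 to 19 reads in each library except FMR1 replicate 2 (79.6%).

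Merging the peaks of the 4 libraries gave 13706 regions. Of these, 1495 held a peak of each of the 4 libraries and 1355 a peak of each library but FXR1 replicate 2. The regions with a peak in 1 library alone numbered 3104 for FXR1 replicate 1, 1505 for FXR1 replicate 2, 1524 for FMR1 replicate 1 and 2003 for FMR1 replicate 2. Both FXR1 replicates marked 2031 regions and both FMR1 replicates 3407. The 1495 regions in both sets were 73.6% of the FXR1 set and 43.9% of the FMR1 set, 2.96 times the 504.9 that independent sets would share (Fisher's exact test over regions, odds ratio 14.2). With 1 library left out, where its antibody's set is that of the other library alone, sharing was 1.27 to 1.67 times expectation. The expectation takes no account of read support, with which overlap rose. Regions with many reads tend to be called with either antibody, so an excess over this expectation was likely in advance.

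**Figure D2:**
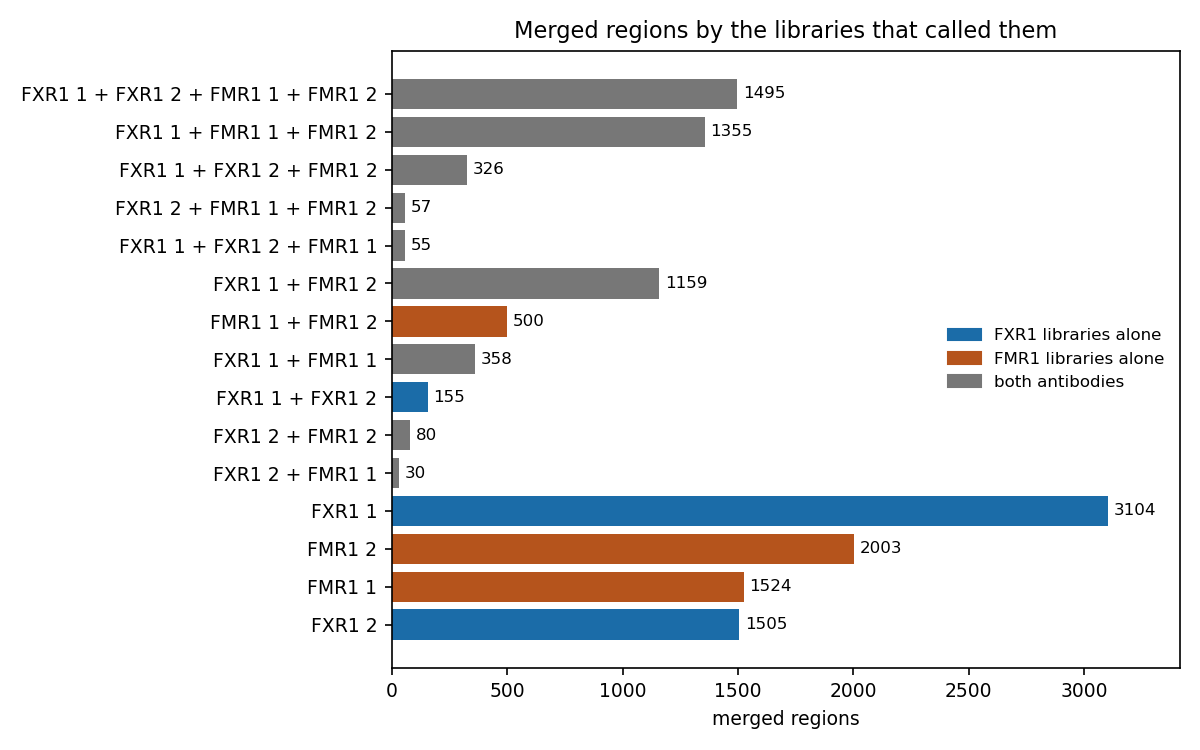
Number of merged regions (x axis) for each combination of libraries that called them (y axis, antibody and replicate number), grouped by how many libraries took part. The combination of all 4 libraries holds 1495 regions, FMR1 replicates 1 and 2 alone hold 500, and FXR1 replicates 1 and 2 alone hold 155.

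Whether libraries of one antibody resembled each other more than libraries of different antibodies had no single answer. By the Jaccard index of merged regions, the pair most alike was FXR1 replicate 1 with FMR1 replicate 2 (40.7%), ahead of the 2 FMR1 replicates (38.1%) and well ahead of the 2 FXR1 replicates (21.0%). The mean of same-antibody pairs was 29.5% and that of cross-antibody pairs 29.4%, a difference of 0.187 points, and of the 3 ways to pair the 4 libraries the crossed pairing gave a larger one (2.91 points). The difference by antibody was −0.93 points at 6 or more reads, −1.40 under the stricter threshold and 1.24 with lists of equal length. A measure free of list length gave a higher value for the antibody. Among regions called in exactly 2 libraries, the pattern odds for same-antibody pairs were 2.46 (bootstrap 95% interval 1.88 to 3.31, counting error only), where 1 means no preference for the antibody. They were 2.03 (1.53 to 2.73) with every deposited peak, 2.29 (1.79 to 2.96) with lists of equal length and 2.74 (1.82 to 4.76) under the stricter threshold. The highest value, 5.48 (2.49 to 11.1), came at 6 or more reads, where 18 regions were of FXR1 alone. With 3 pairings no p under 0.333 is possible. The odds are free of list length but not of detection limits, which followed the antibody. Over 1 input read, 3 reads sufficed to pass in each FXR1 library, against 4 and 6 in FMR1 replicates 1 and 2. The odds therefore cannot tell a preference in binding from a shared sensitivity.

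Regions marked by one antibody alone were the smaller part of each set. Of the regions with a peak in both replicates of one antibody and in neither library of the other, 155 belonged to FXR1 and 500 to FMR1. The mixed pairs that could not follow the antibody numbered 1159 (FXR1 replicate 1 with FMR1 replicate 2), 358 (both replicates numbered 1), 80 (both numbered 2) and 30 (FXR1 replicate 2 with FMR1 replicate 1). When absence was judged on every deposited peak of the other antibody, a setting chosen after seeing the data, 83 FXR1 regions and 500 FMR1 regions remained. The full FXR1 lists add few peaks (8640 of 8666 and 4300 of 4322 had passed), so the FMR1 count could hardly fall. The full FMR1 lists add many (5723 of 9737 and 7457 of 19218 had passed). In 11 of the 83 and in 283 of the 500 the weaker of the 2 replicates had at least 6 reads. Each FMR1 replicate 2 peak past the threshold has at least 6 reads, whereas 3 suffice in the FXR1 libraries. These counts therefore do not compare the antibodies. By the reads of the weaker replicate, the first FXR1 region lay on chromosome 5 at 140090904 to 140090957 (plus strand), with 50 and 94 reads, and 6 of the next 9 lay on chromosome 11 between 65269333 and 65272597. The first FMR1 region by the same order lay in that same chromosome 11 locus, at 65267098 to 65267176 (plus strand), with 129 and 155 reads. The next lay on chromosome 2 at 175664147 to 175664187 (minus strand), with 37 and 44 reads, and on chromosome 18 at 40848813 to 40848887 (minus strand), with 35 and 31 reads. Within 1 kb of that chromosome 2 region, on the same strand, lay a region with a peak in each of the 4 libraries (175664418 to 175664540). A region of one antibody alone can thus lie beside a shared one. All coordinates are of hg19, counted from 1; no gene annotation of that build was used here. These regions were taken in order of the weaker replicate's reads after their values were seen.

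The strongest regions of the antibodies were largely shared. Of the 10 regions per antibody with the highest percentile rank in the lower of its 2 replicates, ranked within each list by the authors' −log10 p and then log2 enrichment, 4 were in both top lists. All 10 FXR1 regions and 9 of the 10 FMR1 regions held a peak in each of the 4 libraries. The first in both lists lay on chromosome X at 47431386 to 47431527 (minus strand), with log2 enrichments of 13.38 and 12.40 in the FXR1 replicates and 8.33 and 7.53 in the FMR1 replicates. The others in both lists lay on chromosome 2 at 175664418 to 175664540 (minus strand), chromosome 5 at 73925052 to 73925223 (minus strand) and chromosome 11 at 117708677 to 117708784 (minus strand). Further FXR1 regions were on chromosome 20 at 10286909 to 10287119 (plus strand, log2 10.20 and 9.10), chromosome 17 at 78442821 to 78442896 (minus strand, 12.81 and 11.96) and chromosome 3 at 49708547 to 49708637 (plus strand, 14.16 and 10.93). Further FMR1 regions were on chromosome 14 at 60063033 to 60063267 (minus strand, 8.02 and 8.14) and chromosome 2 at 68406026 to 68406126 (minus strand, 8.28 and 7.40). The region in the FMR1 list that lacked a peak in FXR1 replicate 2 lay on chromosome 20 at 10287683 to 10287761 (plus strand). Enrichments are relative to each library's own input and depth, 3 reads over 1 input read being worth 6.85 and 6.94 in the FXR1 libraries but 4.51 and 3.48 in the FMR1 libraries, and are not comparable between libraries.

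At the scale of loci, where peaks of any library on one strand were chained at gaps of up to 10 kb, most dense loci were occupied by both antibodies. Of 744 loci with at least 10 peaks, 641 (86.2%) held a peak of each of the 4 libraries, 9 held no FXR1 peak and 0 held no FMR1 peak. The densest lay on chromosome 15 at 25223600 to 25245511 (plus strand), with 29 and 22 peaks in the FXR1 replicates and 26 and 36 in the FMR1 replicates. It was followed by chromosome 9 at 114306077 to 114315969 (plus strand), with 19, 9, 24 and 21 peaks in the same order, and by chromosome 15 at 25266058 to 25281572 (plus strand), with 21, 6, 16 and 25. None of these 3 differed between antibodies in its share of all peaks (Fisher's exact test on peak counts with Benjamini-Hochberg adjustment over 744 loci, adjusted p = 1 for each).

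The share of peaks differed between the antibodies at 11 of the 744 loci by that test (adjusted p under 0.05), higher for FMR1 at 10 and for FXR1 at 1, and 23 had a raw p under 0.05. The 10 FMR1 loci fell into 5 stretches and held 198 FMR1 peaks and 10 FXR1 peaks, with no FXR1 peak at 7 of them. On chromosome 6 from 56350240 to 56505348 (minus strand), 4 loci along 155 kb held 36 and 48 peaks in the FMR1 replicates and 0 and 3 in the FXR1 replicates; the first of these 4, 56350240 to 56397306, had the lowest adjusted p (Fisher's exact test, 1.60e-06). Further along chromosome 6, from 152671451 to 152783973 (minus strand), 3 loci lay within a stretch of 113 kb that held 13 and 30 FMR1 peaks and 0 FXR1 peaks, 2 of the latter 30 outside the loci. The others were on chromosome 2 at 54839423 to 54896646 (plus strand; 11 and 28 FMR1 peaks, 5 and 2 FXR1 peaks), chromosome 7 at 82580102 to 82595613 (minus strand; 5 and 13 against 0 and 0) and chromosome 1 at 39765911 to 39790350 (plus strand; 6 and 10 against 0 and 0). These loci were long, with a median span of 23.0 kb against 2.82 kb for all 744. In each of the 10 the peak share was higher in both FMR1 replicates than in both FXR1 replicates. These loci were picked for few FXR1 peaks, and 7 held none, so this separation was nearly fixed and is no independent support. Over all 744 loci the replicates of the antibodies did not overlap at 276 loci with FMR1 higher and 41 with FXR1 higher, together 42.6%, where chance gives 33.3%. That lean followed a general shift of the shares, since 43.8% and 39.1% of the FXR1 peaks and 54.4% and 52.8% of the FMR1 peaks lay in the 744 loci. With shares taken of the peaks within these loci, a setting chosen after seeing the data, the numbers were 121 with FMR1 higher and 125 with FXR1 higher, together 33.1%. By those shares 8 loci differed, 7 higher for FMR1 and 1 for FXR1.

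The locus with a higher FXR1 share lay on chromosome 11 at 65266551 to 65273406 (plus strand), with 14 and 25 peaks in the FXR1 replicates and 3 and 4 in the FMR1 replicates, a share 5.67 times that of FMR1 (Fisher's exact test, adjusted p = 0.000325). Per 1000 peaks of a library these were 1.62 and 5.81 for FXR1 and 0.524 and 0.536 for FMR1. The peaks of the antibodies lay at different places within it. The 39 FXR1 and 7 FMR1 peaks formed 33 merged regions, of which 8 held both FXR1 replicates, 1 held both FMR1 replicates and 0 held a peak of each antibody. The reads per peak there had a median of 6 in FXR1 replicate 1, 60 in FXR1 replicate 2, 129 in FMR1 replicate 1 and 39.5 in FMR1 replicate 2. Without FXR1 replicate 2 the difference did not pass (Fisher's exact test, adjusted p = 0.579, with 14 against 3 and 4 peaks), and the ratio of shares fell from 5.67 (exact 95% interval 2.51 to 15.04) to 3.05 (1.15 to 8.93). Nor did it pass without FMR1 replicate 2 (Fisher's exact test, adjusted p = 0.0687), where the ratio was 5.75 (1.83 to 29.1) with 39 against 3 peaks.

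The test on loci treats peaks as independent, which covers counting error only, and the loci were defined after seeing the data. Set between the replicates of one antibody, it gave 2 loci for FXR1 (4 at a raw p under 0.05) and 0 for FMR1 (4 at a raw p under 0.05). With peaks chained anew under each setting, the count fell from 11 to 2 without FXR1 replicate 1, to 6 without FXR1 replicate 2 and to 0 without FMR1 replicate 2, and it was 9 without FMR1 replicate 1. It was 1 under a stricter threshold, 2 at 6 or more reads and 0 with lists of equal length. The calls higher for FMR1 fell from 10 to 0 under the stricter threshold, without FXR1 replicate 1, without FMR1 replicate 2 and with lists of equal length, and to 1 at 6 or more reads. Those higher for FXR1 then numbered 1, 2, 0, 0 and 1. With the bounds of the 744 loci kept, a setting chosen after seeing the data, the calls higher for FMR1 numbered 0 under the stricter threshold, 1 at 6 or more reads, 0 and 5 without FXR1 replicates 1 and 2, and 13 and 2 without FMR1 replicates 1 and 2. Pooled over the same 10 loci, which were picked for few FXR1 peaks, the ratio of FXR1 to FMR1 peak share was 0.0514 in the main set (10 against 198 peaks, exact 95% interval 0.0243 to 0.0966, counting error only). It was 0.0745 at 6 or more reads (6 against 175 peaks, 0.0270 to 0.165), 0.0918 under the stricter threshold (7 against 72 peaks, 0.0356 to 0.199) and 0.0385 to 0.0774 with any 1 library left out. Each of these settings left fewer peaks to test. With its bounds kept, the first chromosome 6 locus, at 56350240, had an adjusted p of 0.294 without FXR1 replicate 1 and 0.000167 without FMR1 replicate 2 (Fisher's exact test), and the ratio of shares moved from 0.0300 (exact 95% interval 0.000737 to 0.179) to 0.0902 (0.00222 to 0.537) and 0.0295 (0.000700 to 0.192). Chained anew without FMR1 replicate 2, it was a shorter locus with 9 of the 15 FMR1 replicate 1 peaks and an adjusted p of 0.0687 (Fisher's exact test). The chromosome 2 locus, with its bounds kept, had an adjusted p of 1 under the stricter threshold (Fisher's exact test; 5 and 2 FXR1 peaks against 3 and 9 FMR1 peaks), and its ratio of shares moved from 0.183 (0.0690 to 0.413) to 0.551 (0.184 to 1.52).

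**Figure D3:**
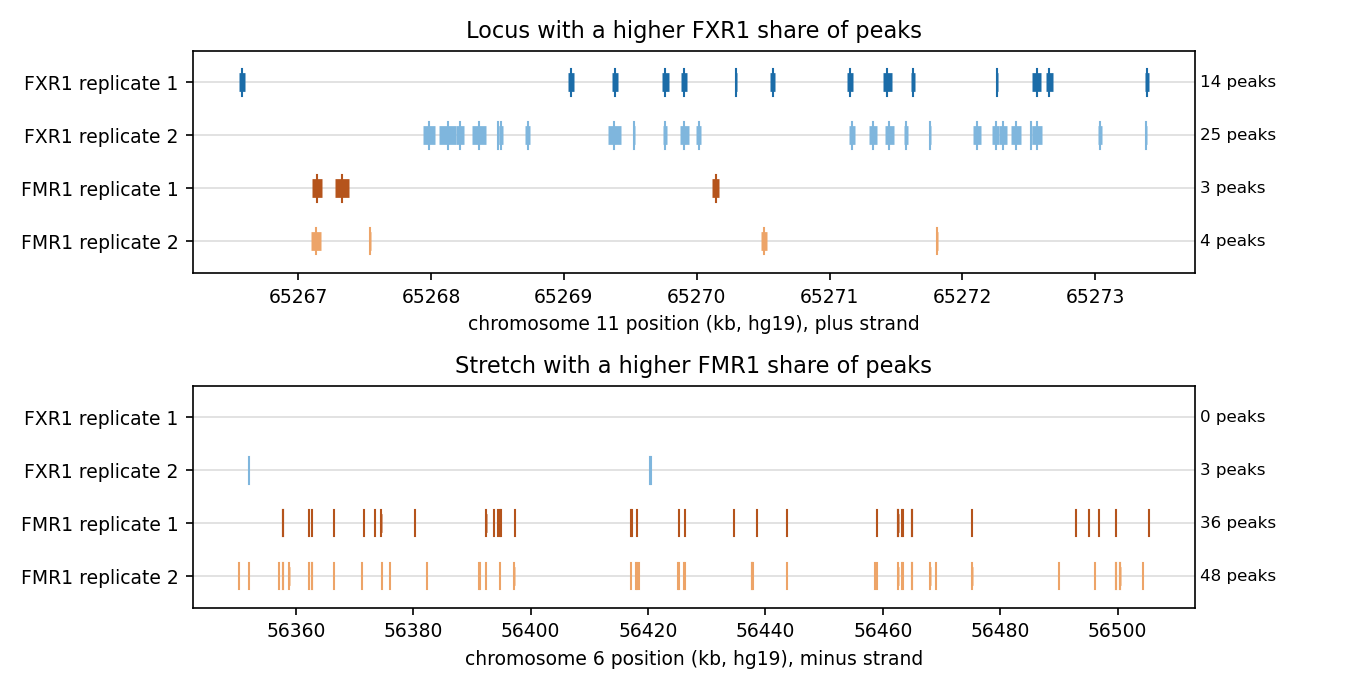
Positions of peaks past the threshold in each library (rows) along chromosome 11 from 65266551 to 65273406 on the plus strand (top) and chromosome 6 from 56350240 to 56505348 on the minus strand (bottom), in kb of hg19; each tick marks a peak's midpoint and each block its width. The top locus holds 14, 25, 3 and 4 peaks and the bottom stretch 0, 3, 36 and 48, from the top row down.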

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

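Of the tests reported here, that of the other loci, that of the other splits of the libraries and the shares within loci were chosen after the result was seen, as were the loci themselves.

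Mitochondrial peaks were left out of the main set, and the sign of their median enrichment over each library's own input differed between the antibodies. Each of the 21 peaks of FXR1 replicate 1 and the 25 of FXR1 replicate 2 had a positive log2 enrichment over input, with medians of 2.80 and 3.64. Of the 30 and 43 peaks of FMR1 replicates 1 and 2, 26.7% and 20.9% were positive, and the medians were −0.58 and −0.81. The difference was not tested, and the sizes of enrichments are not comparable between libraries, since depths differ. The same reads can also give another sign at another depth ratio. Among the mitochondrial peaks 4 of FXR1 replicate 1 and 18 of FXR1 replicate 2 passed the threshold, above their inputs, and 0 of either FMR1 replicate did. Nuclear peaks leaned the same way: 99.7% and 99.5% passed in the FXR1 lists and 58.8% and 38.8% in the FMR1 lists. The contrast therefore cannot be read as particular to mitochondrial RNA.

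The share of peaks differed between the antibodies at 11 loci, 10 of them higher for FMR1. Peaks that fill the FXR1 lists without a partner would lower the FXR1 share at dense loci alike. The median log2 ratio of FXR1 to FMR1 share at the 733 other loci was only −0.25 (quartiles −0.60 and 0.03). Each of the 10 lay at −2.37 or below, but their selection for a low FXR1 share nearly fixed that. With shares taken of the peaks within the 744 loci, 7 loci higher for FMR1 passed, so that the shift may account for some of the 10 calls. At 6 or more reads, where 1 locus higher for FMR1 passed, the 10 loci held 6 FXR1 peaks, all at the chromosome 2 locus, and 175 FMR1 peaks, a ratio of shares of 0.0745 against 0.0514 before, within the earlier exact interval of 0.0243 to 0.0966, while the FXR1 peaks tested fell from 12940 to 5042; as the loci were picked for few FXR1 peaks and each FMR1 replicate 2 peak has at least 6 reads, these values exclude nothing. Weaker FMR1 peaks stay open as a part of the pattern: 51.0% of 198 FMR1 peaks there had 10 or more reads (Wilson 95% interval 44.1 to 57.9%) against 61.2% of 6845 at the other loci, a difference of −10.2 points that met the bound of 10 points set beforehand, though by less than its error; that the interval too should clear the bound was required only after the value was seen. Differences between libraries that do not follow the antibody also stay open. Of the 3 splits of the 4 libraries, 1, the real one, gave 11 loci and the highest other gave 0. These 3 splits are too few for a share under 0.05. The ratio of input to immunoprecipitation depth followed the antibody, with 38.4 and 41.0 for FXR1 and 7.57 and 3.72 for FMR1. Different RNA bound by the proteins, different tissue behind the antibodies and this difference in depth cannot be told apart.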

How the results depend on the processing

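The 11 results were recomputed under up to 16 settings each, 141 values in all, of which 106 kept their call or moved by less than the spread or 1.5 times. Near 0 this allows a change of sign: the difference of Jaccard indices, 0.187 points, was −1.40 under the stricter threshold and −0.93 at 6 or more reads, and the log2 ratio of peaks, −0.10, was 0.40 without FXR1 replicate 2 and 0.091 without FMR1 replicate 2. Settings chosen after seeing the data were 6 or more reads, the handling of touching peaks, absence from every deposited peak, the loci and their settings, and crossed numbers. Sharing of regions by the antibodies stayed above expectation, and overlap of replicates above each of the 100 draws of moved peaks wherever it was run. At 6 or more reads overlap of the shorter list with the longer was 86.9% for FXR1 and 81.2% for FMR1, from 48.9% and 63.0%. The pattern odds ranged from 2.03 with every deposited peak to 5.48 at 6 or more reads. They stayed above 1 under each threshold, length, width and overlap setting, and cannot be had with 3 libraries. Replicate block: the labels do not say that numbers pair the samples, and the correlation of same-numbered deviations over regions was −0.043. With the replicate block the log2 ratio of peaks was −0.10 (exact sign-flip permutation p = 1, smallest possible 0.5), and the pattern odds of pairs by number in place of antibody were 0.552; those of crossed numbers were 0.738; the 3 odds multiply to 1 by construction, so these are no independent check. A split of the libraries by number gave 0 loci and the crossed split 0.

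The log2 ratio of peaks was −1.16 with every deposited peak and −1.35 at 6 or more reads. Regions in both replicates numbered 2153 for FMR1 under the stricter threshold, 837 for FXR1 at 6 or more reads, and 50 for FXR1 and 132 for FMR1 with at least 2 peaks per library. FXR1-alone regions numbered 86 with every deposited peak, 83 when absence was judged on every deposited peak, 18 at 6 or more reads and 0 with at least 2 peaks; FMR1-alone regions numbered 206 under the stricter threshold, 1331 with every deposited peak and 5 with at least 2 peaks. Differing loci numbered 1 (stricter), 18 (every deposited peak), 0 (equal length), 2 (6 or more reads), 3 (gaps of up to 5 kb) and 8 (shares of peaks within loci). Fewer peaks enter under the stricter settings; otherwise the cause was not tested.

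With 1 library left out, its antibody's regions are those of the other library alone: regions in both replicates ranged from 3711 to 8018 for FXR1 and from 5426 to 7036 for FMR1, FXR1-alone regions from 212 to 3263, FMR1-alone regions from 557 to 2545, differing loci from 0 to 9 (2 to 14 with locus bounds kept), the log2 ratio of peaks from −0.60 to 0.40 and sharing over expectation from 1.27 to 1.67. Not run were the alternatives that need an annotation or sequence of hg19. Absolute depth is unknown; peaks of 3 reads were 28.7% and 52.8% of the FXR1 lists, and the threshold admits none in the FMR1 lists.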

Other observations

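Of the hypotheses and tests here, those on the reads of FXR1 replicate 2 and on ranks were chosen after the result was seen; that on locus span was set beforehand.

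Further loci among those with the most peaks, chosen after their values were seen, were occupied in each library. On chromosome 12 at 110783879 to 110788841 (plus strand) the FXR1 replicates had 12 and 9 peaks and the FMR1 replicates 14 and 13. On chromosome 10 at 11372051 to 11378591 (plus strand) the counts were 13, 9, 13 and 12, and on chromosome 16 at 14355878 to 14360592 (plus strand) 14, 9, 10 and 11. Where all 4 libraries had 1 peak in a region (1137 regions), the 5′ ends differed by a median of 7 to 12 nt between any pair of libraries, 9 nt between the FXR1 replicates and 8 nt between the FMR1 replicates.

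Many peaks of FXR1 replicate 2 had no partner. A candidate explanation is the number of peaks made of 3 reads, 2272 of 4300. The share of its peaks that overlapped another library was 29.5% at 3 reads and 92.9% at 6 or more, 63.4 points higher, so that low read support fits the larger part of the pattern. Other peaks without a partner remain at 4 to 5 reads, where 700 of 1030 overlapped, and at 6 to 9 reads, where 527 of 569 did. At 20 or more reads 25 peaks remain without a partner, of which 17 lay in the chromosome 11 locus. No biological explanation was tested.

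It was hypothesised that FMR1 peaks lie along longer stretches than FXR1 peaks, so that loci outside the called ones hold a larger FMR1 share the longer they are. Across 733 loci Spearman's rho of FMR1 share with span was −0.11 (permutation p = 0.00423), against the hypothesis, and at 6 or more reads it was 0.15 across 431 loci (permutation p = 0.00145). Loci are not independent replicates. The settings differ in their peaks and in their loci, and the cause of the change of sign was not tested; the hypothesis was not borne out at the main threshold.

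It was also hypothesised that peak strength follows the antibody. Across the 1495 regions called in all 4 libraries, Spearman's rho of −log10 p was 0.68 between the FXR1 replicates and 0.78 between the FMR1 replicates, but 0.75 between FXR1 replicate 1 and FMR1 replicate 2. The other 3 cross-antibody values were 0.65, 0.54 and 0.63, below both same-antibody values. The lower same-antibody value minus the highest cross-antibody value was −0.0653, so the prediction was not met, but the mean of pairs by antibody (0.730) lay above those by number (0.639) and crossed (0.646). By log2 enrichment rho was 0.56 between the FXR1 replicates and 0.57 between the FMR1 replicates. It was 0.61 between FXR1 replicate 1 and FMR1 replicate 2, above both. The other cross-antibody values were 0.51, 0.39 and 0.47, below both. The hypothesis stays open, as 3 pairings allow no p under 0.333. Regions are not independent replicates.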
